A study of Cricetulus griseus with 4 samples.

How the data were processed

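Gene expression was measured on 4 two-channel arrays. On each array RNA of the chromosomally stable clone RT210B was in channel 1 and RNA of an equal mixture of 2 unstable clones was in channel 2. Unstable mixture 1 held clone LS12 and a further unstable clone and was measured on 2 arrays. Unstable mixture 2 held clone Fe10-3 and a further unstable clone and was also measured on 2 arrays. The mixture and the replicate number of each array were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

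The deposited values are log2 ratios between the channels of an array, 1 value for each of 2304 spots, with no value missing on any array. The labels mention a normalization factor of 3.8 for mixture 1 replicate 2 and of 1.169 for mixture 2 replicate 1. What these factors were applied to, the dyes, the scanner, the background correction and the spot filter are not given in the sources used here. In the deposited log2 ratios, 2 raised to the size of the value was a whole number of hundredths for 100% of spots on each array, within a tolerance of 0.001. Ratios had therefore been rounded to 2 decimals before the logarithm was taken. The deposited columns were not centred, with medians over spots of -0.08 and -0.19 for mixture 1 and of -0.40 and -0.52 for mixture 2. The numerator of the ratio was not settled, because the titles and the descriptions name the pools in opposite order and no dyes are given. Signs are therefore printed as in the deposited columns, and a positive value is not read as higher in either pool. All 4 arrays have the same channel assignment in the labels, and each pair of arrays correlated positively. With no array swapped, a difference between the channels themselves cannot be told apart from one between the pools. No spot intensities were used here, so brightness and signal over background are unknown.

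Spots were joined in adjacent pairs to 1152 probes, each spotted 2 times, and the pair was averaged. This pairing was inferred from the gene annotation, in which the named spots paired without exception. It was checked on the values: across probes, paired spots correlated at r 0.725 to 0.819 on the 4 arrays, against 0.003 to 0.074 for unpaired neighbours. Gene names came from GEO's platform annotation, which lists human genes, while the RNA was labelled as Chinese hamster. Of the 1152 probes, 350 had 1 gene symbol, 8 had several and 794 are unnamed here. The 350 probes stand for 347 genes, of which UBE2R2, GJA1 and ESR1 were on 2 probes each. No gene was named from a probe with several symbols. Hybridisation of hamster RNA to probes annotated with human genes can weaken or misassign a signal, and this was not measured.

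The median over probes was subtracted from each array, so that a value says how far a probe lay from the array's middle probe. The subtracted medians were -0.12 and -0.22 for mixture 1 and -0.44 and -0.53 for mixture 2. The centred log2 ratios were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with 1 mean per mixture over all 4 arrays. Mixture 1, mixture 2, the mean of both mixtures and mixture 1 minus mixture 2 were tested against 0. The fit had 2 residual degrees of freedom and 6.69 prior degrees of freedom. Probes with a Benjamini-Hochberg adjusted p under 0.05 passed, with the adjustment over all 1152 probes. RT210B entered as 1 control sample on every array, so the spread between RT210B cultures is left out of every test. Probes were also counted by size, as at least 2-fold from the array's middle probe with 1 sign on every array concerned. The number of arrays limits the precision: the median SE of a probe was 0.313 (log2) for a mixture, 0.221 for the mean of both and 0.442 for the difference.

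Before the data were examined, 22 gene lists were fixed, and 5 of them had the required 5 measured genes. Those 5 lists were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 5 lists. The other lists had too few measured genes. No gene could be named on a probe for the p53 pathway, mitosis, antioxidant, respiratory chain, glycolysis, blood cell, epithelial, or liver and muscle lists. The telomere and chromatin, NF-kappaB, chaperone, ribosomal, ubiquitin, interferon, immediate early, human chromosome 4 and neural lists had 1 to 4 genes each, which are reported singly. A total of 933 list genes had no probe named with 1 symbol. Some of them may be on probes that are unnamed here or carry several symbols. A further 11 gene groups were drawn up from the gene names on the array, before the values of their genes were seen.

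The rule for named genes was fixed before the data were examined. In a comparison with at least 8 passing probes, the 12 largest positive and 12 largest negative values among passing probes with 1 symbol and the same sign on the arrays of that comparison were named. In a comparison with fewer, the 6 positive and 6 negative probes with the largest smallest size over the arrays were named, as chosen by size, which for the difference is the gap between the arrays of the mixtures. In each tested list the 2 members with the largest mean of both mixtures were named too. Other genes named below were chosen after their values were seen, except the members of small lists.

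The fit was tested on simulated data for 1152 probes with the real spread. With 100 probes changed in mixture 1 by a log2 of 1, 59% passed, and with 100 changed by a log2 of 2, 100% passed. Of 166 calls 7 were false, and 1 call was made in the unchanged mixture 2. In 100 draws of unchanged data camera called a list in 4, and it called a list of 6 genes shifted by a log2 of 1 in 100 of 100. Genes were drawn independently, with array noise alone. In the data the members of a list also differ among themselves, with an SD from 0.191 (apoptosis) to 0.750 (matrix) in the mean of both mixtures. The 100 of 100 therefore does not give the power of camera on these data. Alternatives fixed beforehand were no centring, scaling of the arrays to 1 median absolute value, leaving out each array, a block for the replicate number, robust moderation, an adjusted p under 0.10, the 2 arrays of a mixture alone, a filter on probes whose replicates differed over 4-fold, a filter on missing values and a 1.5-fold size. Alternatives chosen after seeing the data were the restriction to probes whose duplicate spots lay within 0.5 (log2) on all 4 arrays, the removal of a lowess trend (span 0.67) of each array's log2 ratio on the duplicate difference of the other 3 arrays, and the test of each spot as a probe of its own. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for the figures.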

Results

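RNA of RT210B, a chromosomally stable clone, was hybridised on each of 4 arrays together with RNA of 2 pooled unstable clones, to ask whether gene expression differs between stable and unstable clones of 1 genetic background. Mixture 1 (LS12 and another clone) and mixture 2 (Fe10-3 and another clone) were each measured on 2 arrays, with 1152 probes in duplicate spots. From general knowledge, and not from the labels, clones of this naming derive from a Chinese hamster ovary hybrid line that carries human chromosome 4 and was used to study instability after radiation. Values are log2 ratios between the pools, centred on each array's middle probe. Which pool is the numerator is not settled, so genes are described as lying on the positive or negative side of the array's middle, without naming the pool in which they were higher.

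Ratios were widest in mixture 1. The SD over probes was 1.14 and 1.05 (log2) on the arrays of mixture 1, and 0.80 and 0.47 on the arrays of mixture 2. Across probes, the replicates correlated at r = 0.694 (rho 0.714) in mixture 1 and at r = 0.592 (rho 0.613) in mixture 2. Arrays of different mixtures correlated at r = 0.195 to 0.542, where probes are not independent replicates.

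**Figure D1:**
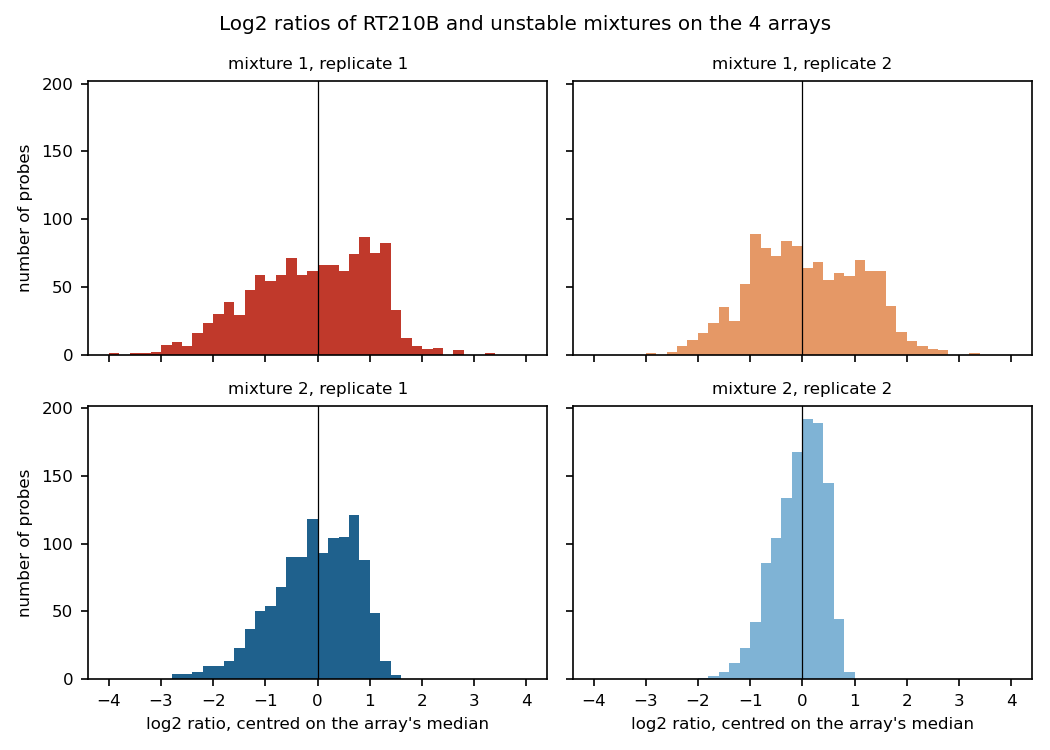
Histograms of the centred log2 ratios of 1152 probes on each of the 4 arrays, with the number of probes on the vertical axis. The SD ran from 1.14 on mixture 1 replicate 1 to 0.47 on mixture 2 replicate 2.

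In mixture 1 the largest named value on the positive side was that of HSP90AA1, the cytosolic stress chaperone. It lay at a log2 of 2.45 (SE 0.348, 2 arrays), or 5.46-fold from the array's middle probe. ELOC, the elongin C subunit of cullin ubiquitin ligases, followed at 2.39 (SE 0.313), and PRDM2, a histone methyltransferase, at 2.14 (SE 0.326). HYAL3 of the hyaluronidase family lay at 1.95, RPS6KA1, a ribosomal S6 kinase downstream of ERK, at 1.82, and ZNF135 at 1.73. HSPA9, the mitochondrial chaperone mortalin, and MAT2A, which makes S-adenosylmethionine, both had a log2 of 1.72. LIMK1, the kinase that inactivates cofilin, and the collagen gene COL11A2 both lay at 1.66, and the transcription factor ETS2 and PDAP1 at 1.61. These 12 genes had adjusted p-values of 0.0061 to 0.0193 in limma with Benjamini-Hochberg adjustment, and each was positive on both arrays of mixture 1. On both arrays of mixture 2, 3 of the 12 were also positive.

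On the negative side of mixture 1 TAF12, a subunit of the general transcription factor TFIID, had a log2 of -2.43 (SE 0.490). This is 5.40-fold from the array's middle probe, with -3.46 and -1.40 on the 2 arrays. ZXDC, a zinc finger regulator, lay at -2.35 (SE 0.358) and SIRT2, an NAD-dependent deacetylase, at -2.27 (SE 0.302). UBE2A, a ubiquitin-conjugating enzyme of post-replication repair, had a log2 of -2.14 and the sulfate transporter SLC26A2 one of -2.09. BLZF1, a Golgi protein, lay at -2.05, the nuclear receptor NR2F1 at -1.94, the membrane skeleton protein ADD3 and the cathepsin CTSO both at -1.92, and the steroid hydroxylase CYP11B1 at -1.91. The Notch ligand JAG1 lay at -1.90 and RPA3, a subunit of the single-strand DNA binding protein RPA, at -1.87. The adjusted p-values of these 12 genes ran from 0.0061 to 0.0117 in limma, and 5 of the 12 were negative on both arrays of mixture 2 as well.

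**Figure D2:**
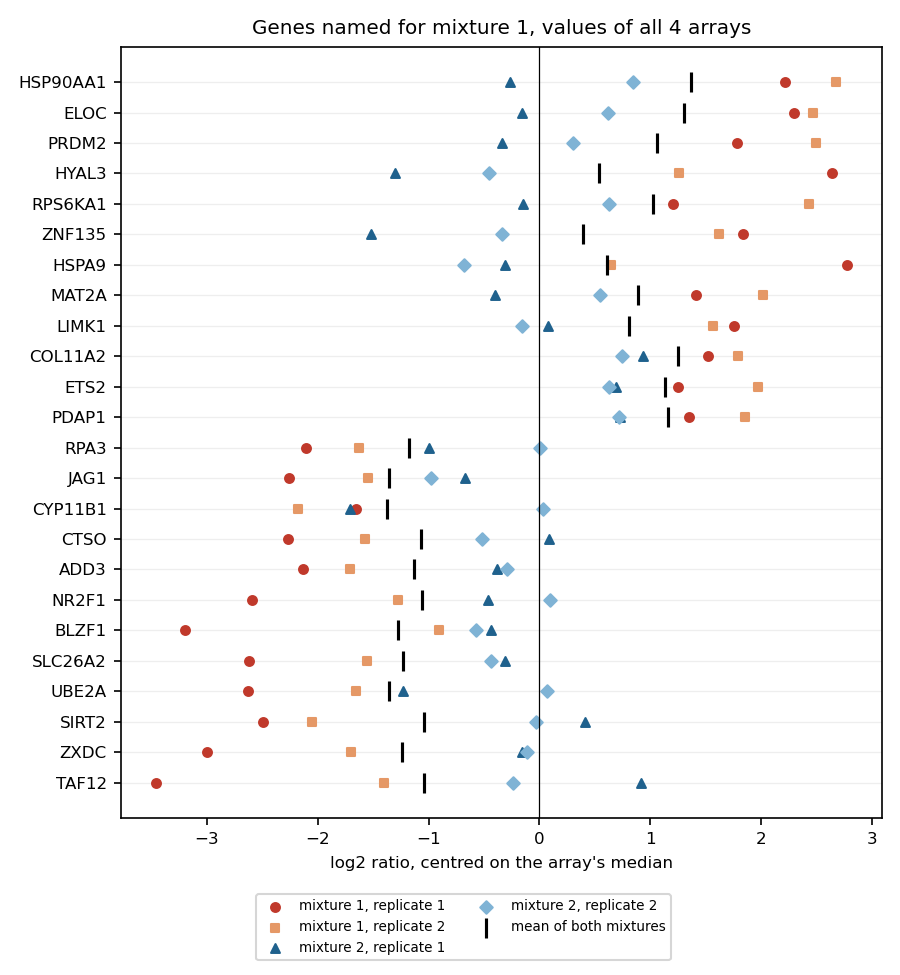
Centred log2 ratios of the genes named for mixture 1 on all 4 arrays (points), with the mean of both mixtures as a black bar. The arrays of mixture 1 lie on 1 side of 0 for each gene, as selected, while those of mixture 2 lie closer to 0 or on the other side for HSP90AA1, HYAL3, ZNF135 and TAF12, among others.

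Among the fixed lists, the cell cycle list had 5 of 8 measured members past the threshold in mixture 1. The kinase WEE1, an inhibitor of mitotic entry, lay on the positive side (log2 1.08), and E2F5 (-1.68), CCNH (-1.22), CDK7 (-1.19) and E2F3 (-0.98) lay on the negative side. CDK7 and cyclin H (CCNH) are partners in the kinase that activates other cyclin-dependent kinases. All 5 apoptosis genes had negative values, with a mean log2 of -0.85 (SD 0.303 over genes), and BID (-1.24) and CASP10 (-1.01) passed. In the matrix list the basement membrane genes NID1 (1.37) and LAMA4 (0.95) passed on the positive side and the protease gene MMP14 (-0.89) on the negative side. In the cytoskeleton and adhesion list CNN3 (1.07) and CDH11 (0.95) were positive and the integrin gene ITGAV (-1.30) was negative. In the DNA repair list LIG4, the ligase of end joining, passed at 1.19, and BRCA1, RAD50, ATM and LIG3 did not. Adjusted over the list alone, 5 cell cycle, 2 apoptosis, 4 matrix, 3 adhesion and 1 DNA repair genes passed. No list was shifted as a whole in limma's camera: the smallest adjusted p was 0.131, for apoptosis (unadjusted p 0.0262), and it was 0.700 with an estimated correlation. The other 4 lists had camera adjusted p-values of 0.392 to 0.652.

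Of the genes from lists too small to test, the chaperone gene DNAJB1 (1.59), the interferon regulator IRF1 (2.83-fold), the ubiquitin-conjugating enzyme UBE2N (1.45), the histone-binding RBBP4 (1.30) and the ribosomal gene RPL31 (0.88) also passed on the positive side in mixture 1. TERT, FOSB, IER2, DUSP5, MAP2K4, S100B and the human chromosome 4 genes KIT and HPGD did not pass in limma in mixture 1, in mixture 2 or in the mean of both. HPGD had log2 values of 0.71 in mixture 1 and -0.58 in mixture 2, and KIT of -0.71 and -0.01.

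In all, 497 of 1152 probes (43.1%) passed in mixture 1 with limma and Benjamini-Hochberg adjustment, 281 on the positive and 216 on the negative side. An unadjusted p under 0.05 was reached by 591 probes, against 57.6 expected with no difference. Of the passing probes 151 had 1 gene symbol, 87 positive and 64 negative. By size, 272 probes were at least 2-fold on both arrays (162 positive, 110 negative), where independent arrays would give 52.2 and 40.2. The positive probes had closely agreeing duplicate spots, with a median difference of 0.096 and 0.159 (log2) on the arrays of mixture 1, against 0.652 and 0.510 for the negative probes. With the trend of the ratio on the duplicate difference removed, an alternative chosen after seeing the data, 236 probes passed (105 positive, 131 negative), 214 of them among the 497, and MAT2A (log2 1.02), COL11A2 (0.90), ETS2 (0.96) and BLZF1 (-1.67) no longer did (limma adjusted p 0.0531 to 0.0856). With the arrays scaled to 1 spread 231 passed and HSPA9 did not, and without replicate 1 of mixture 1 neither HSPA9 (log2 0.65) nor BLZF1 (-0.91) passed. Without that array TAF12 lay at -1.40, NR2F1 at -1.28 and HYAL3 at 1.26, and without replicate 2 RPS6KA1 lay at 1.21, HSPA9 at 2.78 and BLZF1 at -3.195. Over probes with close duplicate spots alone, RPS6KA1 (1.00) and MAT2A (0.89) did not pass. In that setting each array was centred again on the probes kept, which lowered every mixture 1 value by the same amount. Of the named genes, 5 of the 12 positive and 0 of the 12 negative ones were kept.

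**Figure D3:**
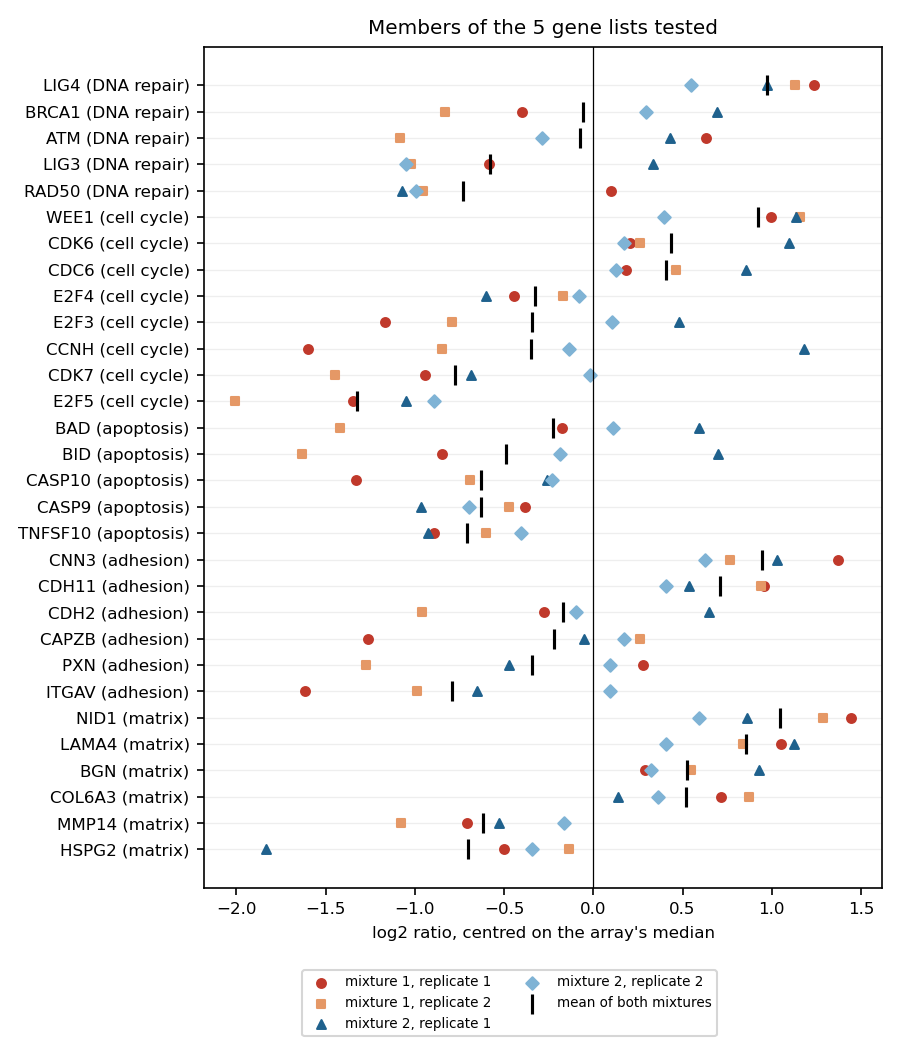
Centred log2 ratios of the genes of the 5 tested lists on all 4 arrays (points) and in the mean of both mixtures (black bar). Each list holds genes on both sides of 0 in the mean of both mixtures, except apoptosis, whose 5 genes lie between -0.22 and -0.71.

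In mixture 2 no probe passed, so genes are given by size. On the negative side NFRKB, a chromatin remodelling subunit, had a log2 of -2.13 and the noncoding RNA XIST one of -1.79, followed by the endothelial cadherin CDH5 (-1.56), the scaffold DLG5 (-1.40), the Polycomb protein PHC2 (-1.31) and the kinase MAPK13 (-1.22). On the positive side were CD99L2 (0.91), the endothelin-converting enzyme ECE1 (0.87), COL11A2 (0.84), ZNF347 (0.76), DNASE1L1 (0.74) and PDAP1 (0.72). Their limma adjusted p-values were 0.172 to 0.254. Without replicate 1 of mixture 2 XIST lay at -1.03, and no other of these 12 values moved by over 1.5 times with either array left out. The count was 0 of 1152 at a Benjamini-Hochberg adjusted p under 0.05 in limma, while 226 probes had an unadjusted p under 0.05, against 57.6 expected by chance. By size, 22 probes were at least 2-fold on both arrays, all on the negative side, where independent arrays would give 5.82. Across probes, the mixture 2 ratio correlated with the duplicate difference at rho = -0.582 on its own arrays and -0.593 on the arrays of mixture 1, against -0.397 and -0.302 for the mixture 1 ratio on its own and the other arrays.

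The count of 0 in mixture 2 was not stable. Fitted on its own 2 arrays, mixture 2 had 113 passing probes (8 positive, 105 negative), among them NFRKB, XIST, CDH5, DLG5, PHC2 and MAPK13 (limma adjusted p 5.46e-08 to 0.00445) and CD99L2 (0.0487). Among these genes the adjusted p followed the size of the value, not the agreement of a gene's 2 arrays. XIST lay at -2.56 and -1.03 on them, but had a smaller adjusted p than CDH5, at -1.79 and -1.32. With the arrays scaled to 1 spread 262 probes passed, including all 12 genes named here, and without centring 206 passed, all negative. No list was shifted in camera (adjusted p 0.564 to 0.742, and at least 0.653 with an estimated correlation), and no list member passed over all probes or adjusted over the list alone. The DNA repair list had a mean of -0.01, a median of 0.07 and a positive direction in camera.

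For the mean of both mixtures only genes on 1 side of 0 on all 4 arrays were named. On the positive side COL11A2 had a log2 of 1.25 (SE 0.204, 4 arrays), CD99L2 1.23, the TGF-beta inhibitor SMAD7 1.17, PDAP1 1.16 and the chaperone DNAJB1 1.15. ECE1, ZNF347, DNASE1L1 and ETS2 each had a log2 of 1.14, GDF10 and the receptor coactivator SRA1 1.13, and ZNF131 1.12. On the negative side were PHC2 (-1.52, SE 0.236), the nucleoside diphosphate kinase NME4 (-1.49), XIST (-1.48), NFRKB (-1.42), JAG1 (-1.36) and the cell cycle regulator E2F5 (-1.33). ATXN1 and BLZF1 both lay at -1.28, MTDH at -1.25, ZXDC at -1.24, SLC26A2 at -1.23 and the leukaemia fusion partner MLLT3 at -1.19. These genes had limma adjusted p-values of 0.00906 to 0.0188. Some of the negative values rest mainly on 1 mixture. ZXDC lay at -2.35 in mixture 1 and -0.13 in mixture 2, SLC26A2 at -2.09 and -0.375, and BLZF1 at -2.05 and -0.505. NFRKB lay at -0.71 in mixture 1 and -2.13 in mixture 2, while PHC2 was similar in both (-1.73 and -1.31).

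The apoptosis genes TNFSF10 (-0.71), CASP9 (-0.63) and CASP10 (-0.63) passed on the negative side in the mean of both mixtures, and BID (-0.49) and BAD (-0.22) did not. In the DNA repair list LIG4 (0.97) and RAD50 (-0.73) passed on opposite sides, and in the cell cycle list WEE1 (0.92) passed on the positive side and E2F5 and CDK7 (-0.77) on the negative side. CNN3 (0.95), CDH11 (0.71) and ITGAV (-0.79) passed among adhesion genes, and NID1 (1.05), LAMA4 (0.86) and MMP14 (-0.62) among matrix genes. Adjusted over the list alone, 3 apoptosis, 2 DNA repair, 3 cell cycle, 3 adhesion and 6 matrix genes passed. In camera the apoptosis list had an adjusted p of 0.245 (unadjusted 0.0491) and the other 4 lists 0.619 to 0.873. With an estimated correlation the smallest adjusted p was 0.894. The adhesion list had a mean of 0.02 with a positive direction in camera, and a median of -0.20.

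In total 446 probes (38.7%) passed in the mean of both mixtures in limma, 250 positive and 196 negative, against 577 at an unadjusted p under 0.05. Of these, 381 had 1 sign on all 4 arrays and 387 also passed in mixture 1, all with the same sign. Only 6 probes were at least 2-fold on all 4 arrays, all negative: XIST, PHC2 and 4 probes that are unnamed here. If the mixtures were independent, each with its own count, 2.10 negative probes would be. With the trend on the duplicate difference removed, 90 probes passed (35 positive, 55 negative), and 10 of the 12 positive but 3 of the 12 negative genes named for this mean no longer did. CD99L2 (1.11) and DNAJB1 (0.86) stayed past the threshold on the positive side, while ZNF131 moved to 0.13 and LIG4 to 0.04. Of the list genes, RAD50 (-0.51), WEE1 (0.70), TNFSF10 (-0.31), CASP9 (-0.57), CNN3 (0.73), ITGAV (-0.61) and NID1 (0.34) did not pass either (limma adjusted p 0.0811 to 0.370). Over probes with close duplicate spots alone, ETS2 (0.50), ZNF131 (0.48), LIG4 (0.33), WEE1 (0.28), NID1 (0.41) and LAMA4 (0.22) did not pass. These values differ from the main ones only by the new centring on the probes kept, which lowered every probe in the mean by the same amount. None of the 12 negative genes named for this mean was kept. Without replicate 1 of mixture 2, 219 probes passed, and LIG4, RAD50, WEE1, TNFSF10, CASP9, CNN3, ITGAV and LAMA4 did not (limma adjusted p 0.055 to 0.216). RAD50 also failed without replicate 2 of mixture 1 (-0.47) and without replicate 2 of mixture 2 (-0.75), as did CASP9 (-0.61 and -0.70), and TNFSF10 failed without the latter (-0.84). TNFSF10 and ITGAV failed without replicate 1 of mixture 1 (limma adjusted p 0.0525 and 0.0533). Without replicate 1 of mixture 1, BLZF1 lay at -0.71. Without centring 558 passed, 124 positive and 434 negative, 320 of them among the 446, and WEE1 (0.59) and LAMA4 (0.53) did not. ITGAV failed with the arrays scaled to 1 spread (limma adjusted p 0.0525), and CASP9 with the replicate number as a block (0.0602).

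**Figure D4:**
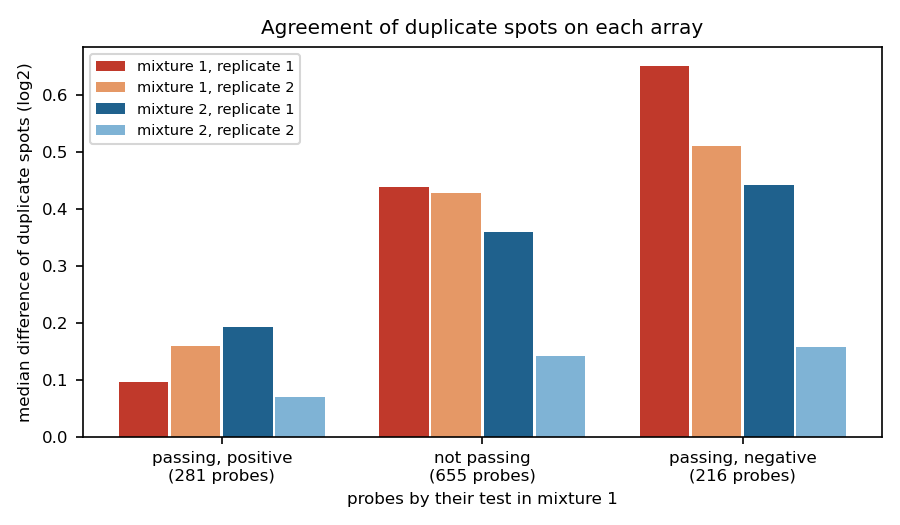
Median difference between duplicate spots (log2) on each of the 4 arrays, for probes grouped by their test in mixture 1. On mixture 2 replicate 1 it was 0.193 for the 281 positive, 0.359 for the 655 other and 0.443 for the 216 negative probes.

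Between the mixtures, genes were named by the widest gap between the arrays of mixture 1 and those of mixture 2, since no probe passed. RBBP4, a subunit of histone deacetylase complexes, had a log2 of 1.30 in mixture 1 and -1.65 in mixture 2, a difference of 2.95 (SE 0.654). It lay at -2.73 and -0.57 on the arrays of mixture 2, and without replicate 1 of mixture 2 its difference was 1.87, the smallest of the 6 positive ones. TEAD2, a transcription factor of the Hippo pathway, differed by 2.94, HYAL3 by 2.83, the metastasis suppressor KISS1 by 2.74, ZNF135 by 2.66 and the protein kinase C gene PRKCH by 2.64. In the opposite direction were SIRT2 (-2.46), CYP51A1, a demethylase of sterol synthesis (-2.25), ZXDC (-2.22), TAF1B of the RNA polymerase I machinery (-1.98), ADD3 (-1.58) and CAND2 (-1.34). TAF12, outside this rule and chosen after its values were seen, differed by -2.77 (SE 0.693, limma adjusted p 0.0911). None of the 1152 probes passed in limma (smallest Benjamini-Hochberg adjusted p 0.0732), 63 had an adjusted p under 0.10, and 275 had an unadjusted p under 0.05. The adjusted p-values of these 12 genes were 0.0732 to 0.115. The cell cycle list had the smallest p in camera for the difference (0.0270, adjusted 0.135, and 0.541 adjusted with an estimated correlation), with a mean of -0.60. The count of 0 was not stable: 47 probes passed without centring and 36 with the replicate number as a block. RBBP4, TEAD2, HYAL3, KISS1, ZNF135, PRKCH, SIRT2 and CYP51A1 passed without centring. They were named for their gap on these same arrays, so this is no separate support. A fit without an array rests on 1 array for that mixture, with no spread of its own, so its count is not set beside the main one here.

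**Figure D5:**
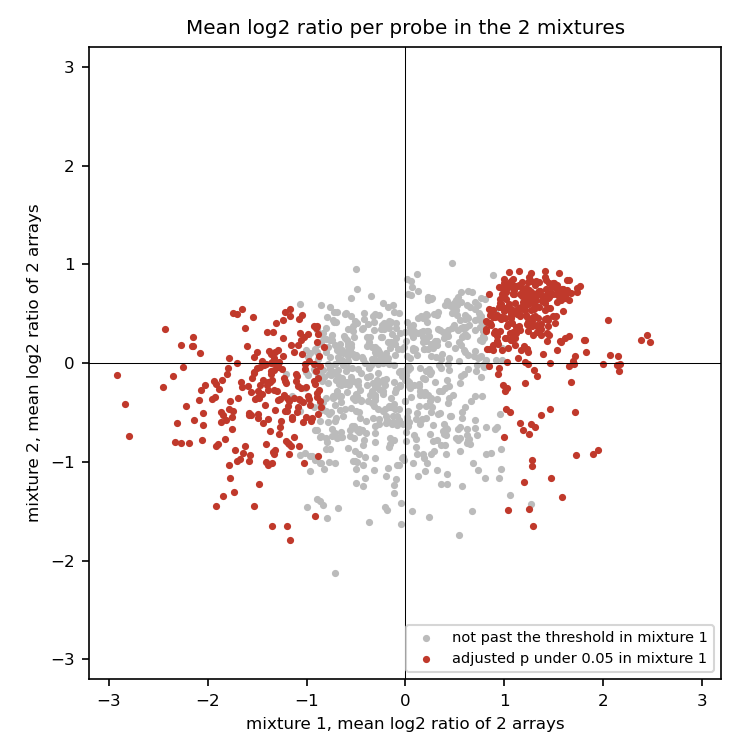
Mean log2 ratio of each of 1152 probes in mixture 1 (horizontal) and mixture 2 (vertical), with the 497 probes that passed in mixture 1 in red. The correlation across probes was 0.411, and of the 497 probes 340 had both arrays of mixture 2 on the same side.

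Across probes the mean log2 ratios of the mixtures correlated at r = 0.411 (rho 0.462), with 67.8% of probes on the same side. Both mixtures were set against RT210B. With no difference between the pools, simulation gave r = 0.003 if RT210B did not vary, and r = 0.668 if 1 RT210B sample varied as much as the arrays did. The observed covariance was 0.235, against 0.227 in the simulation with a varying RT210B sample, so part or all of the relation may come from the shared control. The size of that variation was assumed, and the simulated values follow from it. With the trend on the duplicate difference removed the correlation was 0.203.

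Among the genes on 2 probes, GJA1, the gap junction protein connexin 43, passed on both in mixture 1 with log2 values of -1.81 and -1.05. The probes of UBE2R2 lay at 0.45 and 0.41, and those of ESR1 at 0.63 and -0.62, and neither gene passed in limma.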

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

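The test of mixture 1 ratios against duplicate differences was chosen only after the duplicate differences had been seen, and the refits without the duplicate trend or on close duplicates, and the expected share of opposite signs, were added after seeing the data.

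Of 91 reported probes, 15 had both arrays of mixture 1 on 1 side of the array's middle and both arrays of mixture 2 on the other. Over all probes 133 of 1152 (11.5%) did so, against 28.4% if the mixtures were independent and the replicates of a mixture shared signs as often as they did. The reported probes include genes named for the gap between the mixtures' arrays. RBBP4, TEAD2, HYAL3, KISS1, ZNF135, PRKCH, CYP51A1 and TAF1B entered by that rule, so the share among the 91 cannot be compared with that over all probes. The difference between the mixtures was tested for each of the 15 in limma, and none had an adjusted p under 0.05. The largest were RBBP4 (difference 2.95, SE 0.65, adjusted p 0.0745), TEAD2 (2.94, SE 0.60, adjusted p 0.0732) and HYAL3 (2.83, SE 0.56, adjusted p 0.0732). RBBP4 lay at -2.73 and -0.57 on the arrays of mixture 2, and its difference was 1.87 without the first. KISS1 (2.74), ZNF135 (2.66), PRKCH (2.64) and, with the opposite sign, CYP51A1 (-2.25) had a limma adjusted p of 0.0732 as well. HSPA9 differed by 2.21 (limma adjusted p 0.115), although its values on the arrays of mixture 1 were 2.78 and 0.65. TAF1B differed by -1.98 (limma adjusted p 0.0905), MAPK13 by 1.58 (0.0938), HPGD by 1.29 (0.130) and E2F3 by -1.27 (0.133). BRCA1 (-1.11, limma adjusted p 0.167), BAD (-1.15, 0.212) and TERT (0.72, 0.285) differed least in relation to their error.

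In mixture 1, 43.1% of probes passed, in a positive and a negative set. The centring of an array does not account for the number, since 524 probes passed without centring, 448 of them among the 497. Whether the normalization factors contribute was not tested, because what they were applied to is not given. A ratio that varies with spot brightness may contribute: the mixture 1 ratio correlated with the duplicate difference measured on the other mixture's arrays at rho = -0.302 across probes, just past a bound of 0.3 that was set after the duplicate differences had been seen, and the mixture 2 ratio with that on the mixture 1 arrays at -0.593. With the trend removed 236 probes still passed, between the bounds set for the trend being the whole cause and for its not being so, and this stays open. Brightness itself was not measured, and a difference between the stable and unstable clones stays open, as does a property of 1 of the pooled clones. A difference between the channels cannot be told apart from either, as no array had them swapped.

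The mixtures' mean ratios correlated at 0.411 across probes. Spread of the shared RT210B sample cannot be told apart from a shared difference of the unstable clones, because RT210B's own spread was not measured. The observed covariance was 1.04 times the simulated one, but the simulated one follows from the spread assumed for RT210B and so cannot decide this. A ratio that varies with brightness stays open: the correlation dropped to 0.203 when the trend on the duplicate difference was removed, under the bound set for it, but rose to 0.570 over the 389 probes with close duplicate spots. A shared property of the 4 unstable clones was not tested apart from these, nor from a difference between the channels, which no array had swapped.

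More probes passed in mixture 1 (497) than in mixture 2 (0). Poorer agreement of the mixture 2 replicates cannot by itself make its count the lower one in this fit. The mixtures share the spread of each probe and so have the same SE (median 0.313), which poor agreement would widen for both. The SD of the replicate difference in mixture 2 was 0.746 times that of mixture 1, but that follows in part from the narrower ratios. The replicates correlated at 0.592 in mixture 2 against 0.694 in mixture 1. The narrower ratios on the mixture 2 arrays could account for the smaller count: with all arrays scaled to 1 median absolute value, 262 probes passed in mixture 2 and 231 in mixture 1. With a shared SE, scaling largely evens out the counts by construction, so it does not bear on why the ratios were narrower. Whether the ratios were narrower for technical reasons or because mixture 2 lies closer to RT210B was not tested.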

How the results depend on the processing

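The restriction to probes with close duplicate spots, the removal of the duplicate trend and the test of each spot were chosen after seeing the data. Of 1031 values of 81 single-gene results none turned its sign, but the balance of the calls did, as given below, and other printed genes near 0 were not followed. For genes named with 1 sign on every array of a comparison, leaving out an array or scaling the arrays could not turn it. Of these values, 864 kept their side of the threshold, 112 passed newly and 55 no longer passed. The number of shifted gene lists was 0 under every setting run in the mixtures and their mean, and with close duplicates alone no list had 5 genes left. The filter on missing values removed nothing, and robust moderation moved no count by over 1.5 times. Signal over background was not measured, so its limit is unknown. Where no construction explains a change, the cause was not tested.

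Without centring, 206 probes passed in mixture 2 (0 positive) and 47 in the difference (42 positive, 5 negative), 134 were 2-fold on both arrays of mixture 2 and 31 on all 4, and those of mixture 1 moved from 162 positive and 110 negative to 114 and 162. The split of the calls moved from 281 positive and 216 negative to 232 and 292 in mixture 1, and from 250 and 196 to 124 and 434 in the mean, which includes a shift of every probe by the array medians. Scaled to 1 spread, 231 passed in mixture 1 and 262 in mixture 2, and 79 (28 positive, 51 negative) and 90 were 2-fold on both arrays. On its own 2 arrays mixture 2 had 113. A fit that leaves out 1 array of mixture 1 takes its spread from these same 2 arrays, so for mixture 2 it repeats this one. At an adjusted p under 0.10 the difference had 63. At 1.5-fold the counts by size were 530, 153 and 71.

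With 1 array left out, and a lone array assumed to vary like the others, the counts were 390 to 486 for mixture 1 (200 positive and 252 negative without its replicate 2), 0 to 113 for mixture 2, 219 to 505 for the mean (219 without replicate 1 of mixture 2, and 234 positive and 271 negative without replicate 2 of mixture 1) and 0 to 213 for the difference (213 without replicate 2 of mixture 1). In mixture 2, 113 passed with 1 array of mixture 1 left out, whichever it was, and 33 without its own replicate 2. From 7 to 41 probes were 2-fold on all arrays kept (41 without replicate 2 of mixture 2, 12 without replicate 1 of mixture 1), where fewer arrays need to pass, and the correlation between mixtures was 0.276 to 0.527. Among genes named for the difference that passed without an array of mixture 1, the adjusted p followed the size of the value, not the agreement of arrays. The larger counts of those fits are therefore not comparable with the main ones. Without probes whose replicates differed over 4-fold, 23 passed in mixture 2 and 82 in the difference.

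With close duplicates alone, 389 probes were tested, and each array was centred again on them, which shifted every probe of an array alike. In mixture 1, 135 passed (37 positive, 98 negative, 64 among the 224 main calls that could be tested). In the mean 114 passed (26 positive, 88 negative, 39 among 213), and in the difference 1. On the arrays of mixture 1, of mixture 2 and on all 4, 66 (0 positive), 7 and 3 were 2-fold. The balance of these calls includes the shift, which took RPS6KA1 from 1.82 to 1.00 in mixture 1. The correlation was 0.570. With the duplicate trend removed, 236 passed in mixture 1 (105 positive, 131 negative) and 90 in the mean (35 positive, 55 negative, 81 shared with the 446), 171 (79 positive, 92 negative), 6 and 0 were 2-fold, and the correlation was 0.203. With each spot as a probe, 762 of 2304 passed in mixture 1, and 557, 64 and 14 were 2-fold.

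With the replicate number as a block, 36 probes passed in the difference, 471 in mixture 1, 0 in mixture 2 and 428 in the mean. The replicate differences of the mixtures correlated at -0.098 across probes. Whether arrays with the same replicate number shared a batch is not given in the labels.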

Other observations

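The tests in this part were written down before their results were seen, on groups drawn up from the gene names on the array, while the genes singled out were chosen after their values were seen.

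Of 11 genes of the general transcription machinery, 3 passed on the positive side and 5 on the negative side of mixture 1 in limma, where 43.1% of all probes passed, and TCEA1 (0.32), GTF2H3 (-0.30) and BRF1 (0.14) did not. TAF12 (-2.43), TAF1B (-1.63) and TAF7 (-1.33), all named as factors associated with the TATA-binding protein, were negative, as were CCNH (-1.22) and CDK7 (-1.19) of the TFIIH kinase. ELOC (2.39), GTF3C1 (1.20) and GTF2F2 (1.11) were positive. Of 11 protease genes, 5 passed on the negative side and 1 on the positive side in mixture 1, although 6 of the 11 had positive values. The lysosomal cathepsins CTSO (-1.92) and CTSZ (-1.85), the legumain gene LGMN (-1.22) and the membrane-type metalloproteinases MMP15 (-1.33) and MMP14 (-0.89) were negative, and ECE1 (1.42) was positive. Without replicate 1 of mixture 1, CTSZ lay at -0.72 and TAF12 at -1.40 in mixture 1, and without replicate 2 CTSZ lay at -2.98 and GTF3C1 at 0.79. The 6 protease genes passed in the mean of both mixtures too, where CTSZ moved from -1.01 to -0.45 without replicate 1 of mixture 1 and to -1.58 without its replicate 2. CDK7, CCNH and MMP14 are also members of the lists fixed beforehand.

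In the TGF-beta and BMP group, 9 of 11 genes had positive values in mixture 2, with a mean log2 of 0.35 (SD 0.395 over genes), and camera gave an unadjusted p of 0.0140, an adjusted p of 0.154 and an adjusted p of 0.977 with an estimated correlation. In the mean of both mixtures SMAD7 (1.17), GDF10 (1.13), ID4 (1.03) and SMAD4 (0.67) of this group passed in limma, all positive. With the duplicate trend removed SMAD7 (0.43) and GDF10 (0.49) did not pass, and ID4 and SMAD4 were not followed. The cadherins had a mean of -0.59 in mixture 2 (camera adjusted p 0.263).

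The hypothesis that 1 of the 11 groups was shifted as a whole in the mean of both mixtures was not borne out: the smallest camera adjusted p was 0.772, so no group had one under 0.05. In mixture 1 it was 0.712 and in the difference 0.667. The groups were homeobox factors, TGF-beta and BMP signalling, cadherins, zinc finger proteins, general transcription machinery, replication and repair, MAP kinases, proteases, chromatin regulators, Notch, Hedgehog and Wnt modulators, and blood cell genes.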
